A study of Rattus norvegicus with 4 samples.

How the data were processed

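Gene expression was measured in kidneys of male Wistar rats with an ex vivo model of transplantation from donors deceased by cardiac death. Per the labels' protocols, donor animals weighed 300 to 480 g, and kidneys stayed in the body for 29 min of primary warm ischaemia. They were then flushed and machine-perfused for 3 h with cold University of Wisconsin solution, a preservation fluid for organs. Kidneys of 3 of the 4 groups went on to 30 min of warm perfusion with an oxygenated modified Krebs-Henseleit buffer, a salt solution that stands in for reperfusion. In 2 of these groups, low molecular weight heparin or PPS, which the labels give only by its abbreviation, was added to the cold and the warm perfusate at 10 IU/ml. Each group is represented by 1 array, hybridised with an equimolar pool of RNA from 3 kidneys, and 6 ug of total RNA went into the labelling reaction. The groups are called cold, warm, heparin and PPS below.

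The values are log2 expression values per probe set as deposited by the authors. The submitters' processing notes name GCRMA, a background correction, normalization and summary of Affymetrix probe intensities, and its version is not given in the sources used here. The log2 scale was read from the values, which run from 2.11 to 16.4, because no header states it. GCRMA sets probe sets with little specific signal to a common lowest value: 27.1% of the probe sets were there on the cold array, 27.2% on the warm array, 27.2% on the heparin array and 27.0% on the PPS array. Differences that involve such probe sets are set by the background model, so a floor was applied, as described next. GCRMA also gives all arrays nearly the same distribution of values, so a change in the total amount of messenger RNA per kidney would not be seen.

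Of 31099 probe sets, 57 are Affymetrix controls and were left out of the gene analysis. The platform annotation lists 21268 probe sets, of which 20832 have 1 gene symbol and 436 have several; 9780 probe sets other than controls are unnamed here. Symbols were updated through the Entrez identifier to the RefSeq annotation of the rat assembly GRCr8, in which 20764 of the probe sets with 1 gene were found. The annotation served for names only, and no genome coordinates are printed, because no genome build is named for the array. Probe sets with several symbols were not used. The 14217 genes comprise 9692 with 1 probe set and 4525 with several, for which the probe set with the highest mean over the 4 arrays was taken. The floor was the 50th percentile of all values, 4.51 on the log2 scale, and lower values were raised to it. The 9393 genes above the floor on at least 1 array were analysed, and 9166 of them were above it on all 4 arrays.

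Comparisons were warm minus cold, heparin minus warm, PPS minus warm and heparin minus PPS. With 1 array per group there is no spread between replicates, so these comparisons have no p-value; a gene counted as higher or lower at a log2 difference of at least 1, which is 2-fold. Where 1 side was at the floor, the fold is a lower bound. Where 1 side lay just above the floor, the fold is uncertain as well. To give the counts a scale, 4 unchanged arrays were simulated 100 times, with noise for each gene resampled from the heparin minus PPS differences, divided by the square root of 2, of genes in the same of 20 expression bins. That noise holds any real difference between the supplements. It also comes from the pair of arrays that differed least (SD of log2 differences 0.23), so the simulated counts may be too low for other pairs. Tested on simulated data, the size limit on 1 array against 1 found 58.0% of 200 genes raised 2-fold and all 200 genes raised 4-fold, among 9393 genes, with 25 and 21 unchanged genes past the limit.

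A secondary fit with limma (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05) set the 3 warm-perfused arrays against the cold array, with 2 residual degrees of freedom that hold the supplement effects as well as chance. A further limma fit set the heparin and PPS arrays against the warm array, with 1 residual degree of freedom. Both assume that the lone array varies like the others. On simulated data for the former fit, with 200 changed genes among 9393 and 10 draws per fold, limma found on average 29.8% of genes changed 2-fold, 68.8% of those changed 4-fold and 85.2% of those changed 8-fold, with between 0 and 11 false calls per draw. The changed genes were picked at random and raised equally on all 3 warm-perfused arrays. These shares therefore do not hold for genes that also differ among those arrays.

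For 28 gene lists fixed before the data were examined (pathways, tubule segments and other cell types), the median log2 difference over the genes above the floor was set against 10000 random lists of the same size matched on mean expression. The percentile describes these arrays and is no test of the conditions. Genes are named by a rule fixed at the same time. It takes the 10 largest differences per direction measured above the floor on both sides in warm minus cold, plus 4 with 1 side at the floor. The numbers were 8 and 3 for each supplement against warm, and 6 and 2 for heparin minus PPS. Up to 4 members of each list were added, and symbols that start with LOC or RGD and digits were counted but not named. Genes named outside this rule are marked as chosen after their values were seen.

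Genes picked on warm minus cold and read in heparin minus warm share the warm array, which alone gives a reversal; the same holds for the relation of heparin minus warm to PPS minus warm. Simulated values are given beside each. For the reversal, genes were also picked on a difference that leaves out the warm array and the array being read. Alternatives fixed before the data were examined were other floors (25th and 70th percentile, none), equal medians, quantile normalization, the median of a gene's probe sets, probe sets with shared targets left out, size limits of 1.5 and 2, other limma settings and leaving out each warm-perfused array. Scaling to the poly-A controls, and the heparin or PPS array in place of the warm array, were added after the data had been seen. Precision is limited by the number of arrays, 1 per group. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.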

Results

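Messenger RNA levels were measured on 4 Affymetrix rat arrays, each holding pooled RNA from 3 donor kidneys. The cold array represents kidneys taken after 3 h of hypothermic machine perfusion. The warm array represents kidneys that then received 30 min of warm oxygenated perfusion, and the heparin and PPS arrays represent kidneys treated likewise with 10 IU/ml of the supplement in both perfusates. There were no replicate arrays, so none of the differences between 2 arrays below could be set against a spread between replicates. The RNA pools even out differences between kidneys but do not show their size.

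The arrays had similar distributions, with a median log2 value of 4.498 on the cold, 4.544 on the warm, 4.502 on the heparin and 4.525 on the PPS array. Between 9253 genes (cold) and 9303 genes (warm) were above the floor. Across 9166 genes above the floor on every array, genes that are not independent replicates, Pearson's r was lowest for warm against cold (0.976) and highest for PPS against heparin (0.994). The SD of the log2 differences over these genes was 0.46 for warm minus cold, 0.31 for heparin minus warm, 0.31 for PPS minus warm and 0.23 for PPS against heparin. The 18 probe sets for hybridisation controls, transcripts spiked in after labelling, had a median log2 difference of 0.44 in warm minus cold, -0.28 in heparin minus warm and 0.17 in PPS minus warm. The 24 probe sets for poly-A controls, bacterial transcripts with a poly-A tail spiked into RNA before labelling, stood apart on the cold array. All 24 were higher on the warm array, by a median of 1.25, and the medians were 1.28 for heparin minus cold and 1.10 for PPS minus cold. Among the 3 warm-perfused arrays their medians differed by 0.08 (heparin minus warm), -0.10 (PPS minus warm) and 0.18 (heparin minus PPS). The 3' probe set for beta-actin exceeded the 5' probe set by 2.79 on the cold, 3.22 on the warm, 3.39 on the heparin and 3.19 on the PPS array. The same difference for GAPDH was 0.60, 0.84, 0.72 and 0.81. Both differences, a measure of RNA quality, were smallest on the cold array. A difference in RNA quality therefore cannot be told apart from warm perfusion in warm minus cold.

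**Figure D1:**
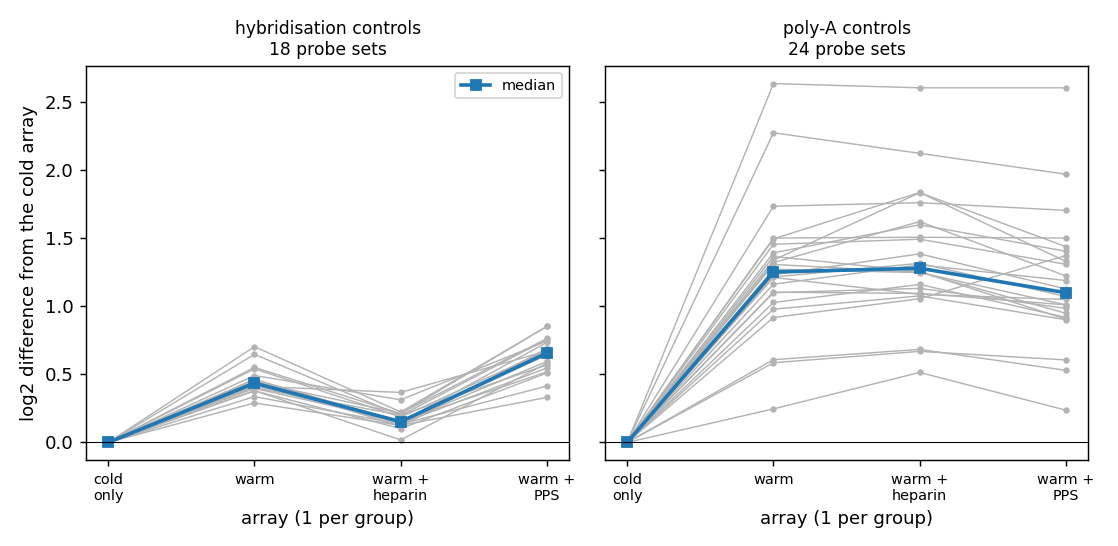
Log2 difference from the cold array (vertical axis) of 18 hybridisation control and 24 poly-A control probe sets on the 4 arrays (horizontal axis); grey lines are probe sets and blue squares are medians. The poly-A medians on the warm, heparin and PPS arrays lie between 1.10 and 1.28 above the cold array, and the hybridisation medians between 0.15 and 0.66.

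The comparison of warm with cold kidneys asked what 30 min of warm oxygenated perfusion adds to cold machine perfusion. Immediate early genes and chemokines were far higher on the warm array, and some genes of the interstitial matrix were lower. Fos, a subunit of the AP-1 transcription factor, had a log2 value of 6.93 on the cold and 14.70 on the warm array, a 218-fold difference. Fosb and Atf3 were at the floor on the cold array and at least 497-fold and 368-fold higher on the warm array. Of 9393 genes, 233 were higher and 109 lower by 2-fold or more, which is 3.64% of genes; unchanged simulated arrays gave on average 19.4 and 21.2. For 50 of these 342 genes 1 side was at the floor. Where a higher gene had other probe sets above the floor, 33 of 35 went the same way, and for lower genes 21 of 22 did. After scaling to the poly-A controls, an alternative chosen after seeing the data, the median of all genes in warm minus cold was -1.19, and 68 genes were higher and 7136 lower. That scaling lowers each warm minus cold difference by about this amount, so that smaller positive differences turn negative.

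Of 30 immediate early genes above the floor, 29 were at least 2-fold higher on the warm array, with a median log2 difference of 3.85, above all 10000 random lists. After scaling to the poly-A controls the median was 2.69. The largest measured differences included Gadd45b (92.7-fold), a stress-induced growth arrest gene, the nuclear receptors Nr4a1 (41.2-fold) and Nr4a2 (34.6-fold), the transcription factor Egr1 (35.6-fold) and the MAP kinase phosphatase Dusp1 (27.7-fold). Of 14 cytokine and chemokine genes, 10 were higher by this size, with a median of 2.49 (1.30 after scaling to the poly-A controls). Cxcl1, a neutrophil chemokine, was at least 46.6-fold higher, and Cxcl10, an interferon-inducible chemokine, was 29.7-fold higher; Cxcl2 and Ccl4, at the floor on the cold array, were at least 27.5-fold and 20.6-fold higher. Of 17 NF-kappaB feedback and target genes, 9 were higher, with a median of 1.06 that turned to -0.12 after scaling to the poly-A controls. Nfkbiz, a nuclear regulator of NF-kappaB, was 39.1-fold higher, and Irf1, Zc3h12a and Tnfaip3 differed by 3.49, 3.24 and 2.76. Outside the lists, Rgs1, a regulator of G-protein signalling, was at least 59.3-fold higher, and Rasd1, a Ras-related GTPase, 23.8-fold higher.

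Some members of other stress lists were also higher on the warm array. Of 17 heat shock genes, 4 were higher by 2-fold or more: Hspa1a (log2 difference 4.24), the inducible form of HSP70, Hspb1 (2.52), Dnajb1 (1.43) and Dnajb4 (1.21). The median of that list was 0.14, at the 99.8th percentile of random lists, and -1.05 after scaling to the poly-A controls. Interferon-stimulated genes had a median of 0.66 with 5 of 18 higher, led by Oasl (3.67), Irf1, Isg15 (1.94) and Ifit2 (1.67), and a median of -0.53 after that scaling. Apoptosis and p53 targets had a median of 0.52 with 6 of 15 higher, among them Plk2 (3.71), Gadd45g (2.70), Tnfrsf12a (1.88) and Cdkn1a (1.87), which encodes the cell cycle inhibitor p21; the scaled median was -0.53. Tubular injury and repair markers had a median of 0.56 with 3 of 14 higher, Hbegf (2.56), Krt19 (1.91) and Krt18 (1.86), and a scaled median of -0.63. TGF-beta and BMP targets had a median of 0.54 with 3 of 13 higher, including Id1 (1.84) and Bambi (1.25), and a scaled median of -0.65. Of 22 hypoxia-response genes, 4 were higher, Adm (2.73), Pfkfb3 (2.20), Ddit4 (1.70) and Egln3 (1.24), while the median of the list was 0.10, or -1.09 after that scaling. In the unfolded protein and integrated stress response list, Ppp1r15a, a phosphatase subunit that reverses the block on translation, was 24.2-fold higher and Ddit3 differed by 1.97, but the median of 17 genes was -0.04. Among 16 clock genes, Nr1d1 (2.42), Per1 (2.20) and Nfil3 (1.14, or -0.05 after scaling to the poly-A controls) passed the size limit, with a median of the list of 0.08 (-1.11 after that scaling). Icam1, a leukocyte adhesion molecule, differed by 1.97 and was the only 1 of 12 endothelial adhesion and activation genes past the limit; the median of these 12 was 0.18 (-1.01).

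Some genes of connective tissue were lower on the warm array. The lower genes named first were picked by the size of their difference, whatever their tissue. The largest measured differences were in Cpne7, a calcium-dependent membrane-binding protein (12.9-fold lower), the elastic fibre protein Fbln5 (9.06-fold), the matricellular protein Smoc2 (7.80-fold), Cygb (6.54-fold), a globin of fibroblasts and pericytes, and Loxl1 (5.14-fold), which cross-links elastin. Adamtsl2 (5.14-fold), Igfbp3 (5.07-fold), Col12a1 (4.92-fold), Dpt (4.87-fold) and Col6a3 (4.51-fold) followed. With the warm side at the floor, Serpine2, Olfml3, Dpep1 and Abca8a were at least 8.81-fold, 8.51-fold, 7.40-fold and 7.0-fold lower. All 8 measured smooth muscle, pericyte and fibroblast markers were lower, 5 of them by 2-fold or more, with a median of -1.16, below all random lists; Col1a2 (-1.43), Pdgfrb (-1.35), Tagln (-1.31) and Col1a1 (-1.29) led. The complement proteases C1s (-1.68) and C1r (-1.45) and the proteoglycan Dcn (-1.13) were lower as well, although the median of 16 complement and coagulation genes was 0.24 (-0.95 after scaling to the poly-A controls) and that of 21 proteoglycan and glycosaminoglycan genes 0.06 (-1.12).

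Most markers of nephron segments stayed within the size limit. All 14 collecting duct markers were higher on the warm array, with a median of 0.62, and 1 passed the size limit, the water channel Aqp4 (1.61). The median for podocyte markers was 0.86, with 2 of 8 past the limit (Nphs1, 1.06, and Wt1, 1.01), that for 10 markers of the thick ascending limb and distal convoluted tubule 0.39, and that for 13 endothelial cell markers 0.34. After scaling to the poly-A controls these 4 medians turned to -0.57, -0.33, -0.80 and -0.85, and Nphs1 and Wt1 to -0.13 and -0.18. As deposited, the medians of the same 4 lists, in that order, were 0.04, 0.35, 0.15 and 0.12 in heparin minus cold. In PPS minus cold they were 0.16, 0.63, 0.32 and 0.04. The higher collecting duct values were thus seen mainly on the warm array, and the lower ones given below for heparin and PPS are set against that same array. Of 20 proximal tubule markers 17 were lower, with none past the limit and a median of -0.23, at the 0.05th percentile; Slc5a2, the SGLT2 glucose transporter, had the largest difference (-0.89). The medians of leukocyte markers (0.03), oxidative stress genes (-0.01), oxidative phosphorylation genes (-0.07), 9 reference genes (-0.04) and 42 cytosolic ribosomal proteins (-0.0032) were within 0.1 of 0 as deposited. Few genes of the red blood cell (3), adrenal (2) and fat cell (3) lists were above the floor, with medians of 0.04, -0.12 and 0.13, and Hbb, a haemoglobin chain, differed by -1.14. Scaled to the poly-A controls, the medians of leukocyte, red blood cell and fat cell markers were -1.16, -1.14 and -1.06.

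**Figure D2:**
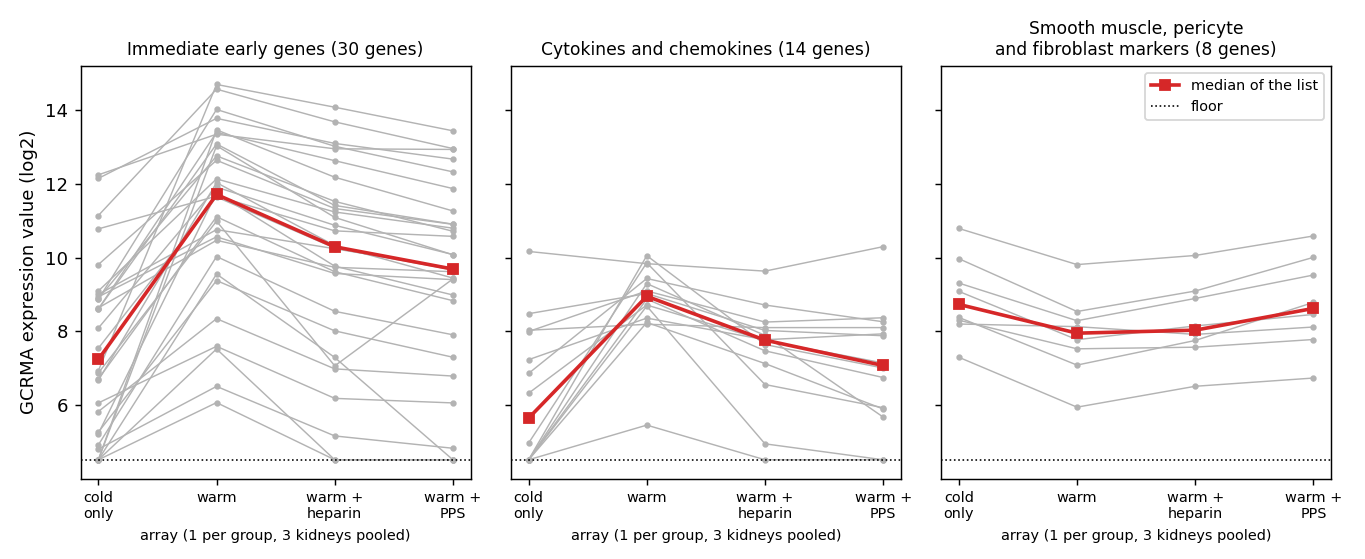
Log2 expression value (vertical axis) on the 4 arrays (horizontal axis) of 30 immediate early genes, 14 cytokine and chemokine genes and 8 smooth muscle, pericyte and fibroblast markers; grey lines are genes, red squares are medians, and the dotted line is the floor at 4.51. Immediate early genes differ by a median of 3.85 between warm and cold and by -1.33 and -1.69 between heparin or PPS and warm.

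All 3 warm-perfused arrays were set against the cold array with limma. At an adjusted p under 0.05 the fit found 0 genes higher and 1 lower, Grhl1, a grainyhead transcription factor that was named because the count was 1 (adjusted p = 0.030 by limma). Its log2 value was 6.27 on the cold array and 2.29, 2.32 and 2.28 on the warm, heparin and PPS arrays, all 3 below the floor, where values are set by the background model, so the size of its difference is not given. The fit took the lone cold array to vary like the other 3. Of 9393 genes, 1523 had an unadjusted p under 0.05. The call of Grhl1 was lost with an intensity trend and robust estimation and when the floor was applied. In single comparisons with the cold array, 110 genes were higher and 86 lower on the heparin array, and 97 higher and 74 lower on the PPS array; 64 genes were higher and 28 lower on all 3. These comparisons share the cold array, and unchanged simulated arrays gave 6.81 (from 1 to 16) and 7.34 (from 1 to 15). Immediate early genes had a median of 2.59 in heparin minus cold and 1.82 in PPS minus cold.

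The comparison of heparin with warm kidneys addressed what this glycosaminoglycan, tested for anti-inflammatory properties, changes in perfused kidneys. Chemokine and immediate early genes, and some interferon-stimulated genes, were lower with heparin than on the warm array. Ccn1, a matricellular early-response gene, was 15.2-fold lower, the chemokines Ccl20 and Cxcl10 were 13.4-fold and 9.88-fold lower, and Oasl was 7.77-fold lower. Of 9393 genes, 36 were higher and 139 lower by 2-fold or more, where unchanged simulated arrays gave 20.3 in each direction. Other probe sets of the same gene went the same way in 15 of 18 cases for lower genes and in 7 of 11 for higher genes.

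All 30 immediate early genes were lower on the heparin array, 19 of them by 2-fold or more, with a median of -1.33. Nr4a3 was at least 8.05-fold lower, and Egr2 (-2.26) and Gadd45b (-1.99) were among the largest, while Fos, named after its values were seen, differed by -0.62. All 14 cytokine and chemokine genes were lower, 7 past the limit, with a median of -0.98, including Cxcl1 (-2.41) and Cxcl2 (-1.41). The median of the NF-kappaB list was -0.63 with 6 of 17 lower past the limit (Irf1, -2.05; Cd83, -1.62), and that of interferon-stimulated genes -0.54 with 4 of 18 (Isg15, -1.37; Ifit3, with the heparin side at the floor, at least 2.90-fold lower). Apoptosis and p53 targets had a median of -0.27, with Cdkn1a (-1.95) and Plk2 (-1.54) among 4 past the limit, and heat shock genes -0.18, with Hspa1a (-1.12) and Hspb1 (-1.03). Medians were -0.22 for tubular injury markers, -0.25 for TGF-beta and BMP targets and -0.16 for hypoxia-response genes, in which Pfkfb3 (-1.45) and Adm (-1.07) passed the limit. Unfolded protein and integrated stress response genes had a median of 0.13, above the middle 95% of random lists (0.04 after scaling to the poly-A controls). Of 17 such genes, 12 were higher, 0 of these past the limit. The 2 lower past it were Ppp1r15a (-1.73) and Ddit3 (-1.22). Icam1 (-1.47) and Hbegf (-1.79), named for PPS below, were lower with heparin too. Collecting duct markers were lower in all 14 cases, with a median of -0.52, podocyte markers had a median of -0.41, leukocyte markers -0.27, endothelial cell markers -0.21 and 10 thick ascending limb and distal markers -0.14. Smooth muscle, pericyte and fibroblast markers had a median of 0.46. Scaled to the poly-A controls, these medians kept their direction, with -1.38 for immediate early and -1.07 for cytokine and chemokine genes. Of the 3 measured fat cell markers, Car3 (-1.78) and Fabp4 (-1.28) were lower.

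Other genes with large differences on the heparin array lay outside these lists, apart from Areg, a tubular injury and repair marker. Akr1b8, an aldo-keto reductase, was 18.5-fold higher than on the warm array, the transporter Slc22a13 8.89-fold, Smoc2 7.13-fold and Cpne7 4.01-fold, followed by Ccdc77 (3.47-fold), the chloride channel Cftr (3.27-fold), the kinesin Kif5c (3.15-fold) and the EGF receptor ligand Areg (3.15-fold). Serpine2, Brcc3-ps7 and Fndc1 were at least 4.15-fold, 2.77-fold and 2.72-fold higher. Among lower genes were the class I histocompatibility gene RT1-CE10 (10.9-fold), the kinase Dapk2 (7.94-fold), the lipase inhibitor Angptl4 (7.13-fold) and Ly6al (5.49-fold), and, with the heparin side at the floor, the kallikrein Klk1c4 (at least 21.3-fold) and RT1-CE5 (at least 7.77-fold). Of 11 RT1 class I genes above the floor, a set chosen after its values were seen, 4 passed the size limit in heparin minus warm. In PPS minus warm 1 passed it, and in heparin minus PPS 5 did. By the share of all genes past the limit, 0.20, 0.24 and 0.05 would be expected. Differences between the pooled kidneys cannot be told apart from an effect of heparin here. RT1 genes, kallikreins and aldo-keto reductases belong to families of near-identical copies, among which array probes can be shared.

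The comparison of PPS with warm kidneys asked the same of the other supplement. Chemokine and immediate early genes were again lower, and some connective tissue genes were higher than on the warm array. Oasl was 16.7-fold lower, with a log2 value of 4.76 on the PPS array, just above the floor. Cxcl10 was 15.3-fold, Cxcl2 12.3-fold and Cxcl1 8.28-fold lower, and Smoc2 was 14.2-fold higher. There were 48 genes higher and 161 lower by 2-fold or more, where unchanged simulated arrays gave 20.6 and 19.9. Other probe sets went the same way in 23 of 25 cases for lower genes and in 6 of 9 for higher genes.

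All 30 immediate early genes were lower on the PPS array, 28 of them past the limit, with a median of -1.69; Egr2 was at least 32.9-fold lower and Atf3 and Gadd45b were 7.78-fold and 6.83-fold lower. Of 14 cytokine and chemokine genes 13 were lower, 9 past the limit, with a median of -1.37, and Ccl20 was at least 18.0-fold lower. The medians were -0.69 for NF-kappaB genes (8 of 17 past the limit; Irf1, -2.28; Nfkbiz, -2.17), -0.47 for interferon-stimulated genes (6 of 18; Isg15, -1.85), -0.32 for apoptosis and p53 targets (4 of 15; Plk2, -2.36) and -0.16 for heat shock genes (4 of 17; Dnajb1, -1.46). They were -0.27 for tubular injury markers (Hbegf, -2.30, but Areg, 1.19), -0.33 for TGF-beta and BMP targets, -0.18 for hypoxia-response genes, -0.19 for endothelial adhesion and activation (Icam1, -1.46) and -0.13 for the unfolded protein and integrated stress response (Ppp1r15a, -2.62). Angptl4 and the lipoprotein gene Apoc2 were 7.78-fold and 7.02-fold lower. Smooth muscle, pericyte and fibroblast markers had a median of 0.78, with Col1a1 (1.70), Col1a2 (1.47) and Col3a1 (1.24) past the limit. Slc22a13 was 11-fold higher, Cpne7 5.69-fold, Dpt 4.69-fold, Fbln5 4.11-fold, Loxl1 4.09-fold, Cygb 3.65-fold and the matrix metalloproteinase Mmp2 3.61-fold, and Serpine2, Olfml3 and Dpep1 were at least 8.03-fold, 4.25-fold and 2.98-fold higher. C1s (1.25), C1r (1.14) and the syndecan Sdc3 (1.23) were higher too. All 14 collecting duct markers were lower (median -0.47), endothelial cell markers had a median of -0.20, podocyte markers -0.14 and proximal tubule markers 0.12. Scaled to the poly-A controls, the medians of immediate early and of cytokine and chemokine genes were -1.57 and -1.26. Those of NF-kappaB, interferon-stimulated, apoptosis, TGF-beta and BMP, and tubular injury genes were -0.58, -0.36, -0.30, -0.22 and -0.16, and those of collecting duct, proximal tubule, and smooth muscle, pericyte and fibroblast markers -0.36, 0.23 and 0.90. Medians nearer to 0 were -0.04 for heat shock, -0.07 for hypoxia-response, -0.08 for endothelial adhesion and activation and -0.02 for unfolded protein and integrated stress response genes, and -0.09 and -0.02 for endothelial cell and podocyte markers.

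**Figure D3:**
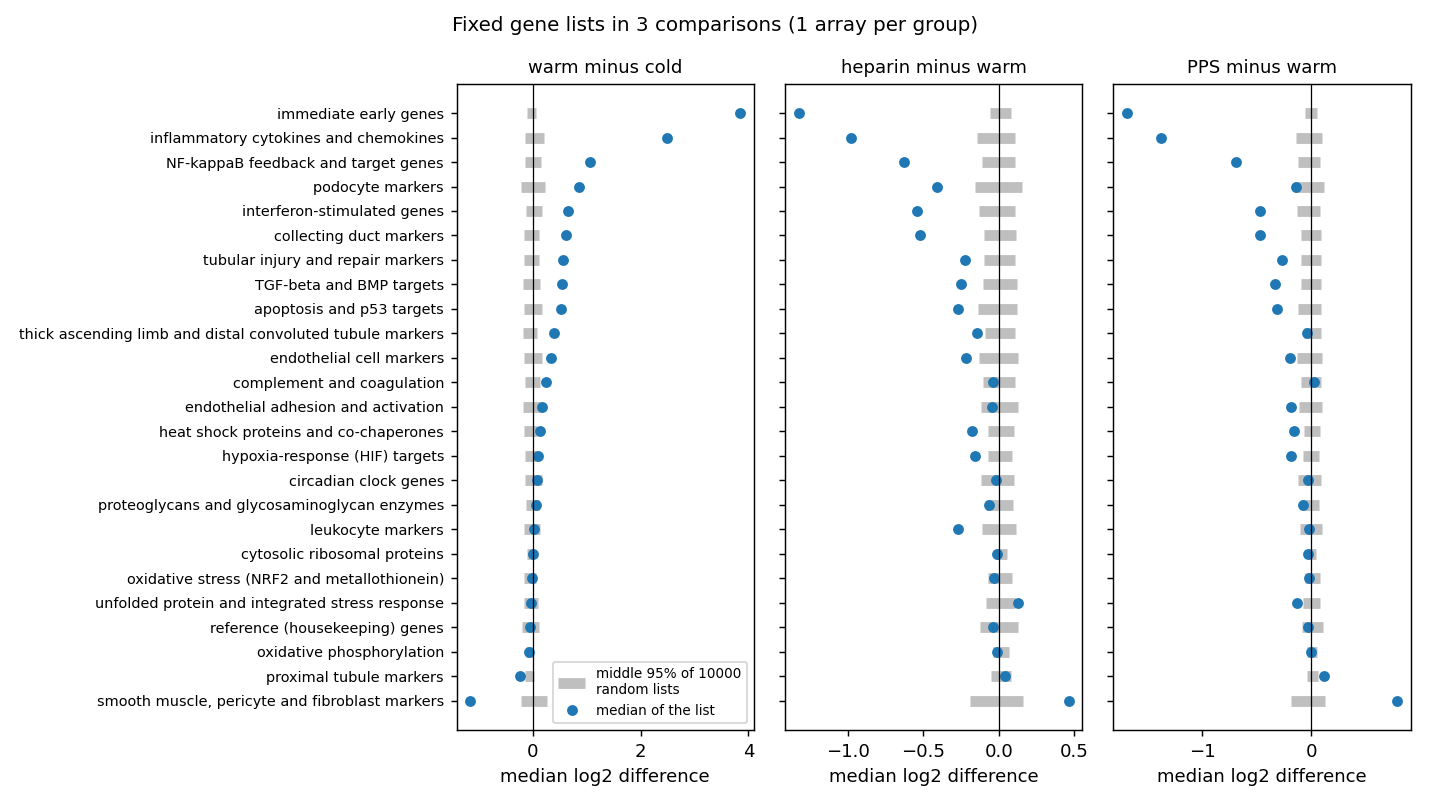
Median log2 difference (horizontal axis, with its own scale in each panel) of the fixed gene lists with at least 5 measured genes (vertical axis) in 3 comparisons; grey bars span the middle 95% of 10000 random lists matched on expression. Immediate early genes lie at 3.85, -1.33 and -1.69, and smooth muscle, pericyte and fibroblast markers at -1.16, 0.46 and 0.78; scaled to the poly-A controls, the warm minus cold medians lie about 1.19 lower, and all those between 0 and 1.06 turn negative.

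The genes that were higher on the warm than on the cold array were read on the supplement arrays to see how far they moved back. Of those 233 genes, 219 had a lower value on the heparin array than on the warm array, with a median of -0.88, and 221 had a lower value on the PPS array, with a median of -1.08. Against the cold array, 81 of them were still at least 2-fold higher with heparin and 76 with PPS. Because the warm array is in both differences, unchanged simulated arrays gave average medians of -0.65 (from -1.39 to -0.05) and -0.66 (from -1.58 to -0.10). Each simulated median is over only the genes that passed the limit by noise, on average 19.4. Its range therefore cannot show how much of the median of 233 genes the shared array gives. With no array shared, 97 genes picked on PPS minus cold had a median heparin minus warm of -0.64, where the middle 95% of random lists lay between -0.03 and 0.03, and 73 of them were lower. Likewise 110 genes picked on heparin minus cold had a median PPS minus warm of -0.65, with random lists between -0.03 and 0.01. The 109 genes lower on the warm array had medians of 0.43 (heparin) and 0.64 (PPS). Simulated unchanged arrays gave 0.59 (from 0.08 to 1.72) and 0.62 (from 0.0032 to 1.77), again over few genes, on average 21.2. With no array shared, 74 lower genes picked on PPS minus cold had a median heparin minus warm of -0.0040, within the middle 95% of random lists (-0.03 to 0.03). The 86 lower genes picked on heparin minus cold had a median PPS minus warm of 0.12, above that of random lists (-0.04 to 0.02).

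The differences of the supplements from the warm array were related across genes, which are not independent replicates. Pearson's r over 9393 genes was 0.74, where unchanged arrays that share the warm array gave 0.50, and the covariance was 0.0838 against 0.0291 in the simulation. Of 139 genes lower with heparin and 161 lower with PPS, 109 were lower with both; independent lists would share 2.38 and simulated unchanged arrays shared 7.58. Of 36 and 48 higher genes 16 were shared, with 0.18 and 7.71 as the corresponding values. The simulations ranged from 1 to 17 for lower genes, below the 109 observed, and from 1 to 16 for higher genes, which reaches the 16 observed. The warm array could not be split, so part of the excess of lower genes may come from it. A limma fit of the heparin and PPS arrays against the warm array found 0 genes at an adjusted p under 0.05, with 940 of 9393 at an unadjusted p under 0.05, and also 0 with an intensity trend and robust estimation, where 825 had an unadjusted p under 0.05.

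**Figure D4:**
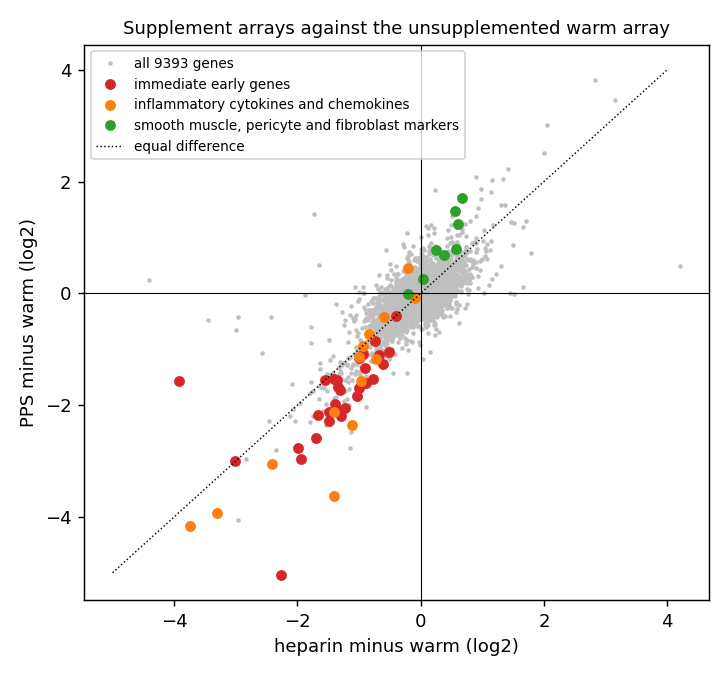
Log2 difference from the warm array of each of 9393 genes with PPS (vertical axis) against that with heparin (horizontal axis); grey points are all genes, coloured points are 3 fixed lists, and the dotted line marks equal differences. All 30 immediate early genes lie below 0 on both axes, and r across genes is 0.74, with 0.50 expected of unchanged arrays that share the warm array.

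The direct comparison of heparin with PPS, at the same concentration in IU/ml, gave the fewest differences. There were 18 genes higher and 28 lower with heparin by 2-fold or more, and unchanged simulated arrays, whose noise was taken from this very comparison, gave 19.97 and 20.15. Scaled to the poly-A controls, the counts were 10 and 50, with a median of all genes of -0.17. Akr1b8 was 13.2-fold higher with heparin, Cxcl2 4.65-fold, the transcription factor Nfil3 3.09-fold, Kif5c 2.90-fold, Gadl1 2.88-fold and Slfn4 2.55-fold, and Egr2 and Fndc1 were at least 6.86-fold and 2.72-fold higher. RT1-CE10 was 7.81-fold, Ccn1 5.14-fold, Dapk2 5.04-fold, RT1-CE12 4.02-fold, Pxmp4 3.63-fold and Mmp2 3.06-fold lower, and Klk1c4 at least 25.03-fold lower. Akr1b10 was at least 8.89-fold lower with heparin, but its other probe set went the other way. Immediate early genes were higher with heparin in 27 of 30 cases, with a median of 0.56 (0.37 scaled to the poly-A controls), and the median for cytokines and chemokines was 0.44 (0.15). Unfolded protein and integrated stress response genes had a median of 0.25 (0.05), above all random lists, and heat shock genes 0.14, which turned to -0.06 after that scaling. All 8 smooth muscle, pericyte and fibroblast markers were lower with heparin, with a median of -0.42.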

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

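All tests in this part were chosen after the results had been seen, except that of a second list of matrix genes, whose members and bounds were written down before their values were read.

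Signals outside the gene comparisons drew attention first. The poly-A control probe sets had a median warm minus cold difference of 1.25, and the other warm-perfused arrays stood at similar heights above the cold array. If hybridisation or array scaling were the whole reason, the hybridisation controls would differ as much, but their median was 0.44, with a range from 0.29 to 0.70. A different amount of control RNA, a separate labelling run and less messenger RNA per total RNA after warm perfusion all remain open, and no array or label separates these possibilities. Scaled to these controls, the median of all genes differed by -1.19. That value follows from the shift of the controls itself, so it cannot decide among them. The cold array alone received no warm perfusion, so a labelling difference and the perfusion cannot be told apart.

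Immediate early genes were lower on both supplement arrays than on the warm array, and the supplement is the difference that the labels give between them. Independent noise of each gene on the warm array would leave a list fixed beforehand near 0, but its median was -1.33 with heparin and -1.69 with PPS, outside the middle 95% of random lists. A smaller share of a cell type would lower its markers about as far as these genes, provided that the marker list holds a single kind of cell. In PPS minus warm the lowest median of a marker list was -0.47, for collecting duct markers. For PPS, this argues against a smaller share of a whole listed cell type. A cell type without a list is not covered, nor is a single kind of cell within a mixed list, such as that of leukocytes. In heparin minus warm collecting duct markers had a median of -0.52, and the 3 measured fat cell markers had -1.28. These 3 split (Car3, -1.78; Fabp4, -1.28; Cidec, 0.07), so they decide nothing either way and a different share of fat cells stays open for heparin. Differences between the pooled kidneys, such as a stronger early response in the warm pool, cannot be told apart from an effect of the supplements, because there was 1 independent pool per group.

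Connective tissue genes were lower on the warm array than on the cold array, with a median of -1.16 for the fixed list. In PPS minus cold that median was -0.14, but in heparin minus cold it was -0.73. A labelling difference of the cold array alone would not shift comparisons that leave that array out. Yet the median was 0.46 in heparin minus warm and 0.78 in PPS minus warm, with 7 of 8 markers higher in each. Such a difference is therefore not the whole reason for how the arrays differ. Its part in warm minus cold cannot be told apart from an effect of warm perfusion, because no other array lacked that perfusion and a supplement could offset either of them. A smaller share of connective tissue in the warm pool may be the reason: 18 measured genes of a second list of interstitial matrix genes had a median of -0.72, below the random range of -0.13 to 0.13, while 7 basement membrane genes had a median of 0.14. In heparin minus cold the median of the second list was -0.39, and in PPS minus cold it was -0.0089, within the random range, with 9 genes lower and 8 higher. However, 14 of the 18, or 77.8%, were lower in warm minus cold, which fell just short of the 80% set beforehand, so that test left the question undecided. Lower expression within the same cells cannot be told apart from a smaller share with 1 independent pool per group.

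Among 3203 unnamed probe sets above the floor, which enter no gene count, 128 were higher and 62 lower by 2-fold or more in warm minus cold. Akr1b10 differed from the warm array in opposite directions with the supplements, by -1.73 with heparin and 1.42 with PPS. The heparin value was at the floor, so -1.73 is only a bound; the difference was not tested, and its other probe set had log2 values of 5.47 (warm), 6.02 (heparin) and 5.27 (PPS).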

How the results depend on the processing

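Scaling to the poly-A controls and the heparin or PPS array in place of the warm array were chosen after seeing the data. Equal medians, quantile normalization, the median of a gene's probe sets and leaving out probe sets with shared targets kept all 8 gene counts within 1.5 times. Of the list medians, 5 moved by more than their bootstrap spread with equal medians, 2 with quantile normalization, 14 with the median of probe sets and 17 with the floor at the 70th percentile; of the named gene differences, 0, 1, 60 and 112 moved by more than the SD of heparin minus PPS at like expression. Scaling to the poly-A controls moved the most: 65 list medians moved and 12 were counted as reversed, and 173 named gene differences moved and 6 were counted as reversed. These counts of reversals leave out smaller differences that also changed sign. In warm minus cold, for example, the median of hypoxia-response genes went from 0.10 to -1.09 and that of leukocyte markers from 0.03 to -1.16. Low signal limits what can be read: a floor at the 25th percentile, or none, moved, among the gene counts, only that of genes higher in heparin minus PPS, to 28. Higher floors and size limits leave fewer genes to pass.

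With the floor at the 70th percentile, genes higher and lower were 106 and 36 in warm minus cold, 6 and 58 in heparin minus warm, 11 and 76 in PPS minus warm, and 4 and 9 in heparin minus PPS. With a size limit of 1.5 they were 102 and 36, 11 and 49, 16 and 75, and 6 and 11; with a limit of 2 they were 66 and 16, 5 and 20, 8 and 35, and 3 and 8. Genes higher than on the cold array numbered 110 with the heparin array in place of the warm array and 97 with the PPS array; the cause was not tested.

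Scaled to the poly-A controls, warm minus cold gave 68 and 7136 genes and heparin minus PPS 10 and 50, since that scaling shifts every gene. The same shift turned warm minus cold medians to -1.05 (heat shock), -0.12 (NF-kappaB), -0.53 (apoptosis), -0.63 (tubular injury), -0.95 (complement), -0.53 (interferon), -0.65 (TGF-beta), -0.80 (thick ascending limb), -0.57 (collecting duct), -0.33 (podocyte) and -0.85 (endothelial), and heat shock in heparin minus PPS to -0.057. It turned Nqo1 to -0.13, Srxn1 to -0.14, Ccn2 to -0.17, Nfil3 to -0.050, Nphs1 to -0.13 and Wt1 to -0.18 in warm minus cold.

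Without a shared array, the reversal medians were -0.64 (heparin) and -0.65 (PPS) for higher genes and -0.0040 and 0.12 for lower genes, where the shared warm array no longer contributes. For higher genes picked on warm minus cold, which share the warm array, the medians were -0.88 (heparin) and -1.08 (PPS). With only genes above the floor on all arrays, these became -0.79 and -0.89. Under that filter, the medians without a shared array were -0.59 and -0.50. The cause was not tested.

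The limma fit of warm-perfused arrays against cold called 1 gene lower, and 0 with an intensity trend and robust estimation (1460 at an unadjusted p under 0.05) or with the floor (1534). With all 14217 genes it called 60 higher and 183 lower, and limma reported zero variances, which the common lowest value gives. Leaving out the warm, heparin or PPS array gave 0 genes higher and 0 lower each time, with from 1038 to 1429 at an unadjusted p under 0.05. With each array alone against the other 3, the fit called few or no genes for any array, which does not show which array stands furthest apart. With 4 splits no share under 0.05 can be reached. Over genes above the floor on all arrays, the SD of the log2 differences from the cold array was 0.46 (warm), 0.36 (heparin) and 0.34 (PPS). From the warm array it was 0.31 for heparin and 0.31 for PPS. No paired analysis was possible because each group has 1 array.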

Other observations

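Some single genes of the fixed lists differed between heparin and PPS. The fat cell markers Car3 and Fabp4 differed by -1.18 and -0.95 in heparin minus PPS, and Hbb by -1.02. Among clock genes, Dbp and Per3 were lower with heparin than with PPS, by -1.34 and -1.0, and Nfil3 was higher, by 1.63, while the median of the 16 clock genes was -0.03. The proximal tubule anion transporter Slc22a7 differed by -1.18.

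Genes of oxidative stress defence differed little as a group in warm minus cold, with a median of -0.01, yet Gsr, glutathione reductase, differed by -1.28, Nqo1 by 1.06 and Srxn1 by 1.05, and the last 2 turned to -0.13 and -0.14 when scaled to the poly-A controls. The proteoglycan Vcan differed by -1.43 with heparin and -1.13 with PPS from the warm array.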
